A study of Homo sapiens with 16 samples.

How the data were processed

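Guide RNA abundance was measured in a loss-of-function CRISPR screen of HCT116 cells by sequencing guide cassettes amplified by PCR from genomic DNA. Each of the 4 groups (MYC 5' UTR reporter or control EGFP reporter, bright or unsorted) had 2 replicates, and every replicate was measured with GeCKO v2 libraries A and B, which makes 16 samples in 8 deposited columns, each stacking the 2 libraries. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, genomic DNA came from a kit for unsorted cells and from another isolation method for sorted cells, so that step differs between bright and unsorted cells in both lines.

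The deposited values are a signal per guide that was normalized by the authors, and MAGeCK is named in the submitters' processing notes without a version. The aligner, the read trimming and the MAGeCK settings are not given in the sources used here. In the deposited signal the lowest value was 1, and each value minus 1 summed to 1000000 over library A in every column, so the values are reads scaled to 1000000 per library (RPM) with 1 added. Every value minus 1 was a whole multiple of the worth of 1 read (100.0% within 0.05 reads in each library and column), which gave totals of 10243515 to 21696511 reads per library. Reads from PCR without molecular identifiers are not independent molecules, so depth covers counting error only. The table as held here ends inside library B, in the middle of a guide, which was dropped; the last complete gene was TGM1, and the rest of library B was not analysed here. It held 63777 guides of library A and 47603 of library B. For genes with guides in library A alone (2658) fewer guides were tested than for those with both (16069).

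Guides are identified by the names in the deposited table. Of 18775 gene symbols, 17305 matched a current symbol and 1376 an older one in a RefSeq gene table (assembly GRCh38.p14, used for names and for which genes neighbour each other), and 94 matched none. Symbols are printed as deposited. The 24 gene names that had turned into calendar dates (144 guides) could not be assigned and were excluded from tests. The 1864 microRNA loci (7288 guides) were tested as genes, and the 1000 non-targeting guides, all in library A, served as background. Guide sequences and genome positions were not used here.

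Values were set to normalized reads, (deposited value - 1) multiplied by a common depth of 14.23 (library A) or 15.47 (library B) reads per RPM, because the pseudocount of 5 and the minimum mean of 20, fixed before the data were examined, were meant for values on the scale of reads. The same settings on the deposited scale are given as an alternative, in which the minimum mean applies to RPM, so that it left out more guides and tested 5430 genes. Log2(value + 5) was fitted per guide with limma 3.58.1 (R 4.3.3, trend in the prior variance) on all 4 groups, without a replicate block. A fold change on this scale understates the change of low guides. Guides were ranked by moderated t, and genes with at least 3 guides (19788) were tested by robust rank aggregation (alpha 0.1, exact null for uniform guide ranks, one-sided in each direction), with Benjamini-Hochberg adjustment per direction and a threshold of 0.05. Mean log2 changes and standard errors came from limma on gene means over guides, and the changes are given relative to the median gene of the comparison. Each standard error pools the spread over all 4 groups and so assumes it to be equal in both lines. Mean abundances are RPM averaged over the guides of a gene, with the SD over 2 replicates. The comparisons were bright against unsorted in each line, the difference of these between lines, and unsorted against unsorted between lines.

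In total 30 gene lists were tested with limma's camera (preset correlation 0.01) on gene means, with Benjamini-Hochberg adjustment over lists within a comparison. Camera with an estimated correlation and fry were alternatives. The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 15 genes with the smallest p for enrichment and the 8 for depletion in each comparison with bright cells, if their mean change kept that direction with either bright replicate, the 5 in each direction for unsorted cells, EIF5A, DHPS, DOHH and MYC in every comparison, and the 2 to 4 leading members of each list described. NELFA, EIF5AL1, SIX5 and subunits of TFIID, SET1/MLL, NELF and eIF3 named outside that rule were chosen after their values were seen. The results of some genes that the rule named are not reported here, though they stay in the counts.

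The alternatives were other pseudocounts (1 and 20), filters (none, and a mean of at least 100), rescaling to the non-targeting guides (library A) or to the median guide, a fit on the samples of a comparison alone, a replicate block, each library alone, each replicate left out, ranking by fold change, other values of alpha (0.05 and 0.25), the strongest guide of each gene left out, a threshold of 0.25, and limma on gene means. The deposited scale, limma voom on the recovered reads, and each library alone for the lists were chosen after seeing the data. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

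The procedure was tested on simulated data for the real guides (19759 genes tested). For bright against unsorted MYC 5' UTR cells it recovered 12.2% of genes raised by a log2 change of 1, 68.0% of those raised by 2 and 98.0% of those raised by 3, and 14.0% of genes raised by 2 through part of their guides, drawn at random, with 1 call among unchanged genes. For the difference between lines the shares were 0.0%, 44.0%, 87.8% and 8.0%, with 0 calls among unchanged genes, and 0 calls were made in the 2 comparisons simulated without a change. The simulated noise was drawn independently for each guide and sample, so no unchanged guide had a shift shared by both replicates. In the real control line the covariance of changes between replicates was 0.591, against 0.045 in the simulation. These shares and counts of false calls therefore need not hold for the real data.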

Results

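The screen measured which gene knockouts were carried more or less often by cells with a bright reporter. HCT116, an established human colon cancer cell line, carried EGFP, a green fluorescent protein, either under the control of the MYC 5' UTR (the untranslated leader of the MYC messenger RNA) or as a control reporter. Both lines received the GeCKO v2 collection, pooled lentiviral guide RNAs that direct the Cas9 nuclease to human genes and microRNA loci, in its libraries A and B. Guides were read out by amplification from the genomic DNA of bright sorted cells and of unsorted cells. The 16 samples formed 4 groups (each reporter line, bright or unsorted) with 2 replicates each, and each replicate was measured once with each of the 2 libraries. Between 10243515 and 21696511 reads stood behind each library, with a median of 136 to 322 reads per guide. In library A, 16.3% and 14.0% of guides had no read in the 2 bright replicates of the MYC 5' UTR line, against 5.60% and 6.68% in those of the control line. The labels do not say whether replicates came from separate cultures, so the spread between these samples may be technical. Limma on gene means measures changes against that spread. The p-values of robust rank aggregation measure how far the guides of a gene agree in rank, with guides as units. The spread between samples enters them only through the order of the guides. Genomic DNA of bright and of unsorted cells was extracted by different methods, so within a line sorting and extraction cannot be told apart. Log2 changes are given relative to the median gene, which lay at -0.10 in the MYC 5' UTR line, 0.07 in the control line, -0.17 for their difference and -0.07 between unsorted cells, on a scale with 5 reads added to each value.

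The first comparison asked which knockouts were over- or under-represented among bright cells of the MYC 5' UTR line. Guides against 11 of 19788 genes were enriched, and 5 of these genes (TAF1, TAF5, TAF7, TAF8 and TAF12) encode subunits of TFIID, the general transcription factor that binds core promoters. TAF5 guides rose by 2.68 ± 0.35 (SE) on the log2 scale, or 6.39-fold, from a mean of 12.8 ± 5.34 to 56.8 ± 14.7 RPM per guide (SD, n = 2). TAF12 rose by 2.52 ± 0.27, TAF7 by 2.25 ± 0.24, TAF1 by 2.19 ± 0.24 and TAF8 by 1.04 ± 0.38, with 0.49 for TAF8 in bright replicate 1 and 1.59 in bright replicate 2. Guides against EIF3L, a subunit of the translation initiation factor eIF3, rose by 2.62 ± 0.31, from 12.7 ± 2.07 to 40.9 ± 2.48 RPM (SD, n = 2), with 1.60 in library A and 3.61 in library B. Other enriched knockouts were ASH2L (1.85 ± 0.21), a core subunit of the SET1/MLL histone H3 lysine methyltransferases, CREBBP (1.97 ± 0.25), a histone acetyltransferase, DBR1 (2.45 ± 0.32), which debranches intron lariats, and CMIP (1.81 ± 0.34). The libraries differed for ASH2L (0.74 in library A and 2.91 in library B) and DBR1 (3.88 and 0.98), and in library B alone TAF12 had 1.29, CREBBP 1.12 and CMIP 1.00. NFE2L2, which encodes the transcription factor of the oxidative stress response NRF2, rose by 2.78 ± 0.35, but its library A guides averaged 5.87 ± 0.83 and its library B guides -0.35 ± 0.29. Its mean abundance in bright cells was 858 ± 1010 RPM (SD, n = 2), so the replicates differed by more than their mean.

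Robust rank aggregation over the guides of a gene gave adjusted p = 3.7e-05 for TAF1, 0.000123 for TAF5, ASH2L and EIF3L, 0.000696 for TAF7, 0.00122 for NFE2L2 and 0.00601 for CMIP. The values were 0.00676 for CREBBP, 0.0223 for DBR1 and 0.0447 for TAF8 and TAF12. All 11 changes had the same sign with either bright replicate. Genes next in rank did not pass, among them TMEM67 with 2.56 ± 0.41 (adjusted p = 0.194), and COASY, which completes coenzyme A synthesis, and POLR3K, a subunit of RNA polymerase III, with 1.05 and 2.19 (each adjusted p = 0.217). With library B alone COASY had -0.43. Robust rank aggregation called 0 genes depleted, with 1034 at an unadjusted p under 0.05, and limma voom followed by the same aggregation also called 0. Limma on gene means called 4 genes lower and 9 higher. The top-ranked genes for depletion, among them OR13C8, BCL2L15, hsa-mir-4436a, SLC22A23, WTIP, hsa-mir-628 and GAB1, had adjusted p = 0.717 and changes from -2.81 (hsa-mir-628) to -0.38 (BCL2L15), and with library B alone BCL2L15 and GAB1 had 0.58 and 0.13. Of the 11 calls, 2 stayed with library A alone, 3 with library B alone and 3 without the strongest guide of every gene. Calls were also lost without either bright replicate or either unsorted replicate of this line. Ranking guides by fold change left 1 call and limma voom gave 7, while TAF1 and ASH2L stayed past the threshold in 24 of 26 other settings each, TAF12 in 4 of 26 and TAF8 in 4 of 25.

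EIF5A, named in the study's title, encodes a translation factor that relieves ribosome stalling, and DHPS and DOHH encode the enzymes that convert one of its lysines to hypusine. In bright cells of the MYC 5' UTR line their guides had mean changes of 1.21 ± 0.40, 1.10 ± 0.37 and 1.74 ± 0.49, and none of the 3 passed over all genes (robust rank aggregation, adjusted p = 0.787, 0.935 and 0.935). Mean abundance of EIF5A guides was 14.8 ± 4.46 RPM in unsorted and 39.4 ± 9.23 RPM in bright cells (SD, n = 2), and with library B alone DHPS had -0.14. Mean abundance of DOHH guides was 6.95 ± 0.777 and 19.5 ± 4.98 RPM, and that of DHPS guides 8.68 ± 3.51 and 22.2 ± 0.075 RPM. The rises in mean abundance of DOHH, EIF5A and DHPS rested largely on single guides. A library A guide of DOHH went from 0.0 and 2.18 RPM in the unsorted replicates to 73.8 and 56.8 RPM in the bright ones. For EIF5A a library A guide went from 15.3 and 20.9 to 174 and 92.0 RPM, and for DHPS a library A guide from 18.7 and 7.85 to 66.0 and 75.2 RPM. The other guides had log2 changes from -2.88 to 2.79 for DOHH, from -0.34 to 1.81 for EIF5A and from -0.72 to 2.47 for DHPS, relative to the median guide. Adjusted over the list alone, all 3 genes passed, which is not independent evidence, because the list was chosen from the study's title. As a list the hypusine pathway rose by a mean of 1.35 (camera, adjusted p = 0.00689; adjusted p = 0.361 with an estimated correlation). In the control line the same guides had 0.63 ± 0.40, 0.15 ± 0.37 and 0.53 ± 0.49, with a list mean of 0.44 (camera, adjusted p = 0.452). Guides against MYC itself had 0.41 ± 0.36 in the MYC 5' UTR line and 0.21 ± 0.36 in the control line, both with adjusted p = 1, and with library A alone -0.21 in the MYC 5' UTR line.

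**Figure D1:**
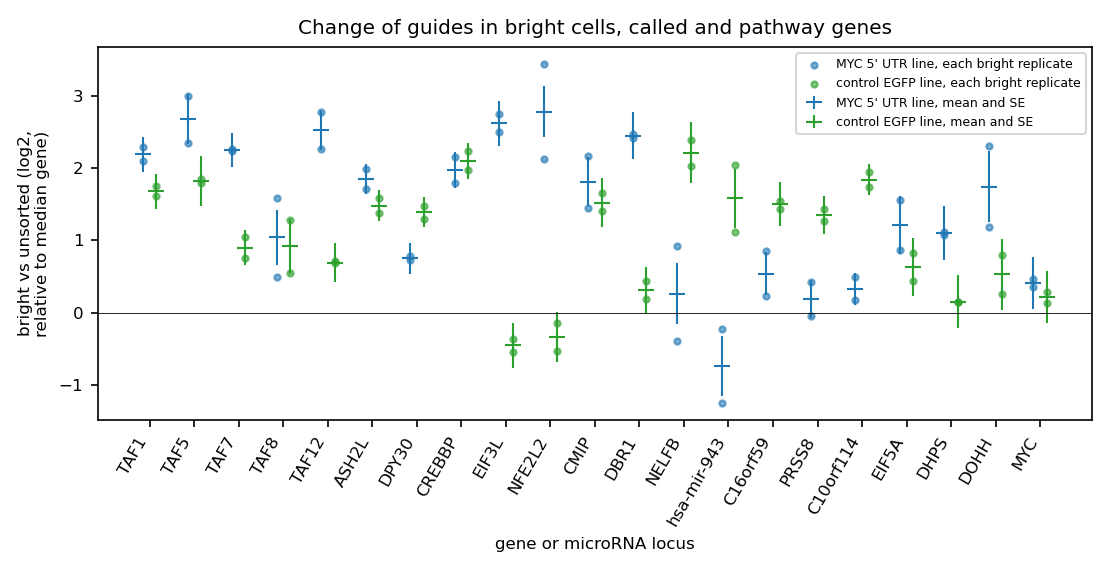
Change of guides in bright against unsorted cells (y axis, log2 relative to the median gene) for named genes called in either reporter line, the hypusine pathway and MYC (x axis). Crosses with bars are means and standard errors, points are the 2 bright replicates, blue is the MYC 5' UTR line and green the control line; EIF3L stands at 2.62 in blue and -0.45 in green, and NELFB at 0.26 and 2.21.

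Of the 30 gene lists fixed before the data were examined, 4 rose and 1 fell in bright cells of the MYC 5' UTR line by camera. The large subunit ribosomal proteins rose by a mean of 0.47 (adjusted p = 0.000497; adjusted p = 0.327 with an estimated correlation), with 32 of 45 members above the median gene. No member passed over all genes, and adjusted over the list alone RPL10 (2.25 ± 0.42), RPL10A (0.73 ± 0.30) and RPLP1 (1.24 ± 0.36) did. The list of SAGA and histone acetylation genes rose by 0.45 (adjusted p = 0.00244; adjusted p = 0.361 with an estimated correlation), with 15 of 20 members above the median gene. In it CREBBP passed over all genes and adjusted over the list alone, and TADA1, a SAGA subunit, had 0.69 ± 0.20. The mTORC1 inhibitors, negative regulators of a growth-controlling kinase complex, rose by 0.55 (adjusted p = 0.0453; adjusted p = 0.361 with an estimated correlation), and 0 of 12 members passed over all genes or over the list alone. Their leading members by rank were DDIT4 (2.83-fold), TBC1D7 (-0.29 ± 0.44) and STK11 (1.61 ± 0.42). The microRNA biogenesis genes fell by a mean of 0.48 (adjusted p = 0.0394; adjusted p = 0.631 with an estimated correlation), with 3 of 15 members above the median gene. Their leading members, TNRC6A (-1.69 ± 0.48), a silencing scaffold bound to Argonaute proteins, and PRKRA (-1.69 ± 0.60), a partner of Dicer, did not pass.

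Of the initiation factors, 1 of 38 was called (EIF3L), and adjusted over the list alone EIF3F, EIF3H and EIF3L passed. The list mean was 0.24 (camera, adjusted p = 0.141). The small subunit ribosomal proteins had a mean of 0.03 and a median of -0.01 (adjusted p = 0.951) and the elongation and termination factors -0.08 (adjusted p = 0.849). The ribosome rescue and quality control genes had a mean of -0.05 with camera's direction up (adjusted p = 0.986), the cytosolic aminoacyl-tRNA synthetases 0.23 (adjusted p = 0.459), the MYC network -0.08 with a median of 0.10 (adjusted p = 0.986) and the p53 pathway 0.29 (adjusted p = 0.468). With an estimated correlation 0 lists passed, with 4 at an unadjusted p under 0.05, and fry passed 0. The 5 lists became 1 without bright replicate 1, 3 without bright replicate 2 and 2 without unsorted replicate 1 of this line.

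The same comparison in the control line gave the background for EGFP fluorescence without the MYC leader. Guides against 12 genes or loci were enriched, led by NELFB, a subunit of the negative elongation factor NELF that holds RNA polymerase II near promoters. NELFB guides rose by 2.21 ± 0.42, or 4.63-fold, from 12.4 ± 0.425 to 63.4 ± 6.45 RPM (SD, n = 2). Guides against CREBBP (2.10 ± 0.25) rose, as did those against DPY30 (1.39 ± 0.21) and ASH2L (1.48 ± 0.21), both core subunits of SET1/MLL methyltransferases. Guides against the TFIID subunits TAF5 (1.82 ± 0.35), TAF1 (1.68 ± 0.24) and TAF8 (0.92 ± 0.38) rose too. TAF8 had 1.28 in bright replicate 1 and 0.55 in bright replicate 2, ASH2L had 0.48 in library A and 2.48 in library B, and C16orf59 had 0.65 and 2.36. Other calls were hsa-mir-943 (1.58 ± 0.41), a microRNA locus inside NELFA on chromosome 4, C16orf59 (2.83-fold), PRSS8 (1.35 ± 0.26, and 0.86 in library A), a membrane-anchored serine protease, and C10orf114 (1.84 ± 0.22, 3 guides). Guides against the host gene NELFA had 2.04 ± 0.33 (adjusted p = 0.118).

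By robust rank aggregation the adjusted p was 6.9e-05 for NELFB, 0.00121 for CREBBP, 0.00127 for TAF5 and DPY30 and 0.00183 for hsa-mir-943. It was 0.00283 for C16orf59, 0.0048 for TAF1, 0.00484 for TAF8, 0.00906 for ASH2L, 0.0159 for PRSS8 and 0.035 for C10orf114, and all 12 changes had the same sign with either bright replicate. NELFCD, another NELF subunit, had 1.61 ± 0.31 (adjusted p = 0.0696), HOOK2 1.57 ± 0.38 (0.0702) and ARHGAP4 1.23 ± 0.46 (0.0749). Robust rank aggregation called 0 genes depleted, with 1054 at an unadjusted p under 0.05. Limma voom with the same aggregation also called 0, and limma on gene means called 0 lower and 2 higher. The top-ranked genes for depletion were CLDN12, EAPP, SLC22A23 and TUBA1B (each adjusted p = 0.409), DEPTOR (0.507), RSC1A1 (0.525) and SPARCL1 and PSG5 (0.710), with changes from -2.04 (TUBA1B) to -0.62 (DEPTOR). Of the 12 calls, 4 stayed with library A alone, which called 5 genes, and 1 when guides were ranked by fold change, which called 4. With library B alone 2 of the 12 stayed, as did 2 without the strongest guide of every gene. All guides of hsa-mir-943 were in library A, so this locus could not be tested with library B alone. Calls were also lost without bright replicate 1, bright replicate 2 or unsorted replicate 2 of this line. TAF8 turned to -0.01 with library A alone and had 1.85 with library B alone, and without bright replicate 1 of this line 1 gene was called depleted.

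Both lines called ASH2L, CREBBP, TAF1, TAF5 and TAF8. These 5 compare with 0.0067 genes for independent lists (one-sided Fisher's exact test, p = 1.4e-14), and the lines shared no control library. The spread of each guide was estimated from both lines together, however, so the 2 lists were not independent and this p-value may overstate the overlap. With each line fitted alone, 8 and 12 genes were called, 7 and 9 of them among the 11 and 12. Across 19788 genes, which are not independent replicates, the changes in the 2 lines had a Pearson correlation of 0.255 and a Spearman correlation of 0.249. Of the 11 genes called in the MYC 5' UTR line, 7 had an unadjusted p under 0.05 in the control line, and of the 12 called there, 8 had one in the MYC 5' UTR line.

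**Figure D2:**
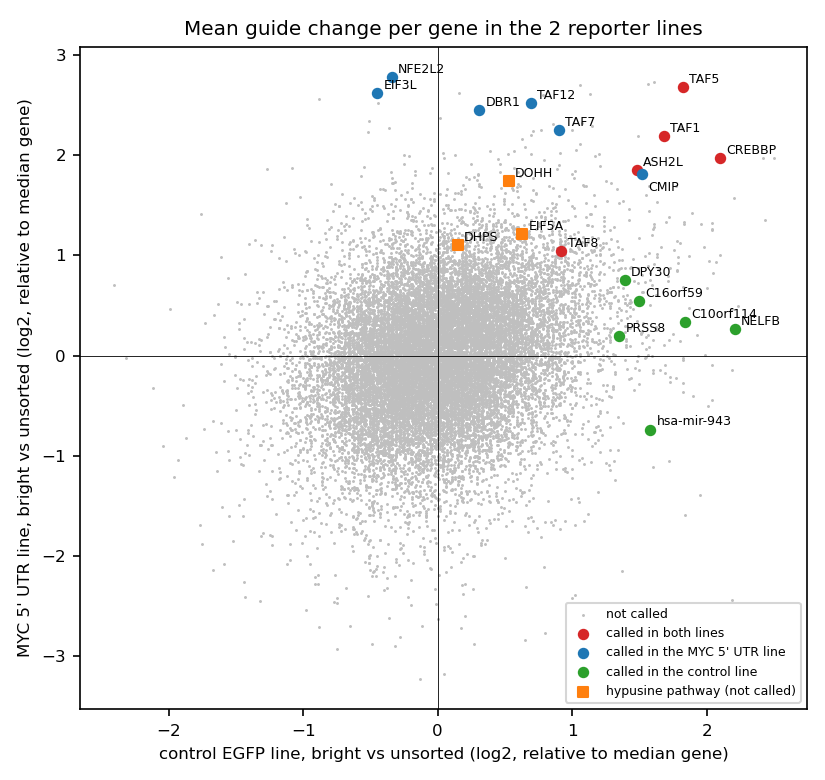
Mean guide change of each gene in bright against unsorted cells of the control line (x axis) and of the MYC 5' UTR line (y axis), both log2 relative to the median gene. Red points are the 5 genes called in both lines, blue the 6 called in the MYC 5' UTR line alone, green 6 of the 7 called in the control line alone, orange squares the uncalled hypusine pathway and grey all other genes; EIF3L and NFE2L2 lie at 2.62 and 2.78 on the y axis and below 0 on the x axis.

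In bright cells of the control line 4 lists rose and 2 fell by camera, and each had an adjusted p of 0.279 with an estimated correlation. The SAGA and histone acetylation list rose by a mean of 0.50 (adjusted p = 0.000282). In it CREBBP was called, and adjusted over the list alone the members that passed included CREBBP, TADA1, USP22 (1.06 ± 0.26) and CCDC101 (1.31 ± 0.27). The large subunit ribosomal proteins rose by 0.31 (adjusted p = 0.0153), with 33 of 45 members above the median gene and 0 called. The chaperonin list, subunits of the TRiC and prefoldin folding complexes, rose by 0.38 (adjusted p = 0.0436), with 11 of 14 members above the median gene, including TCP1 (0.81 ± 0.48) and PFDN5 (0.69 ± 0.29). The core spliceosome rose by 0.27 (adjusted p = 0.0436), with 26 of 34 members above the median gene, including SNRNP200 (1.00 ± 0.37) and U2AF2 (1.32 ± 0.42). The list of eIF2B and integrated stress response genes fell by 0.44 (adjusted p = 0.0153), with 1 of 13 members above the median gene; EIF2B2, a subunit of the eIF2 exchange factor, had -0.99 ± 0.30 and the stress kinase EIF2AK3 -0.74 ± 0.22. The mTORC1 activators fell by 0.39 (adjusted p = 0.0345), with 3 of 14 members above the median gene, and RRAGC and RPTOR had -1.05 ± 0.33 and -0.74 ± 0.29. No member of these last 5 lists passed over all genes or over its list alone. Fry, which does not compare a list with other genes, passed 4 lists, and the 6 lists became 1 without bright replicate 2 and 3 without unsorted replicate 2 of this line. Initiation factors had a mean of 0.02 and microRNA biogenesis genes 0.01, both with camera's direction down (adjusted p = 1).

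**Figure D3:**
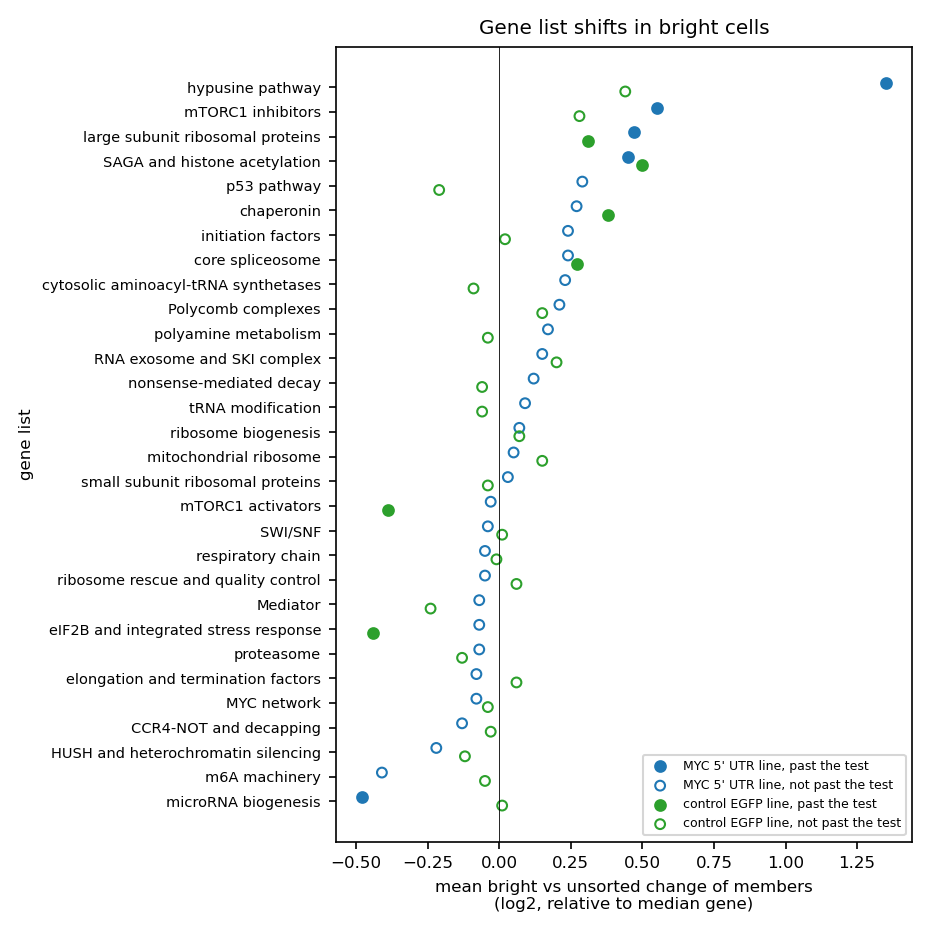
Mean change of the members of each of the 30 gene lists (y axis) in bright against unsorted cells (x axis, log2 relative to the median gene), blue for the MYC 5' UTR line and green for the control line. Filled points passed camera with a preset correlation of 0.01 after adjustment and open points did not; the hypusine pathway lies farthest right at 1.35 in blue, and with an estimated correlation 0 lists passed in either line.

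The test of the difference between the lines asked which knockouts acted more on the MYC 5' UTR reporter than on EGFP as such. EIF3L and NFE2L2 rose more in the MYC 5' UTR line, and the change of hsa-mir-943 was lower there than in the control line. For EIF3L the difference was 3.09 ± 0.44 (robust rank aggregation, adjusted p = 0.000493), and from 1.49 to 3.74 over 25 other settings. EIF3L had 2.62 ± 0.31 in the MYC 5' UTR line and -0.45 ± 0.31 in the control line, and a difference of 2.41 in library A and 3.71 in library B. Its guides were also lower in unsorted cells of the MYC 5' UTR line than in unsorted control cells, by -1.53 ± 0.31 (adjusted p = 0.659), and by -0.12 on the deposited scale, which left out the guides with low counts and tested 5430 genes. For NFE2L2 the difference was 3.13 ± 0.49 (adjusted p = 0.000965), with 6.09 in library A and 0.12 in library B. For hsa-mir-943 the difference was -2.30 ± 0.59 (adjusted p = 0.0234), with -0.74 ± 0.41 in the MYC 5' UTR line, and its abundance was 12.1 ± 3.14 RPM in bright MYC 5' UTR cells and 77.1 ± 5.68 RPM in bright control cells (SD, n = 2). The differences of these 3 had the same sign with either pair of bright replicates.

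Several genes called in 1 line alone had no call for the difference. DBR1 had a difference of 2.15 ± 0.46 (adjusted p = 0.657), TAF12 1.84 ± 0.38 and TAF7 1.37 ± 0.34 (each 0.911), CMIP 0.29 ± 0.48 (0.997), and NELFB -1.94 ± 0.59 (0.130). Over 25 other settings the adjusted p of NELFB ranged from 0.00055 to 1, its change from -2.68 to -1.25, and it passed in 5: library B alone, the deposited scale, and without MYC 5' UTR unsorted replicate 1, control bright replicate 2 or control unsorted replicate 1. C10orf114 had -1.50 ± 0.31 (0.718), DPY30 -0.62 ± 0.29 and C16orf59 -0.95 ± 0.42 (each 0.932), and PRSS8 -1.16 ± 0.37 (0.994). Next in rank above the control were KIFAP3 (1.84 ± 0.56, adjusted p = 0.165), a kinesin adaptor, ABI3BP (2.24, 0.326), and SLC35E2, EIF3H, KIAA1841, TES, GNB2L1, TTR and KRTAP13-2 (each 0.327). Among these, GNB2L1, the ribosomal scaffold now called RACK1, had 1.90 ± 0.40, and the eIF3 subunit EIF3H 0.59 ± 0.39 (-0.07 with library A alone). DHPS had -0.45 with library B alone. PTPRB had an adjusted p of 0.482, and DST, DHRS4L2 and DNAJC8 one of 0.609. Below the control, HES4 had -2.68 ± 0.68 (0.130) and hsa-mir-4262 -2.95 ± 0.45 (0.178), and SNAI3, C15orf39, PRODH and MRS2 had adjusted p = 0.645. EIF5A, DHPS and DOHH had differences of 0.59 ± 0.57, 0.96 ± 0.52 and 1.22 ± 0.70 (adjusted p = 0.909, 0.911 and 0.998), and MYC 0.21 ± 0.50 (1).

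Camera passed 0 of 30 lists for the difference, with 5 at an unadjusted p under 0.05, and fry passed 0. The list means were 0.92 for the hypusine pathway, 0.23 for the initiation factors, 0.38 for eIF2B and the integrated stress response, 0.37 for mTORC1 activators and -0.48 for microRNA biogenesis (each adjusted p = 0.262). Limma on gene means called 0 genes in either direction, and robust rank aggregation had 994 and 1050 at an unadjusted p under 0.05. The 2 positive calls became 0 without MYC 5' UTR unsorted replicate 1 or either control bright replicate and 1 without MYC 5' UTR unsorted replicate 2, and the negative call was lost without either MYC 5' UTR bright replicate, MYC 5' UTR unsorted replicate 2 or control bright replicate 1 and became 2 without MYC 5' UTR unsorted replicate 1, control bright replicate 2 or either control unsorted replicate. Without the strongest guide of every gene, or with no filter on low guides, 0 genes were called in either direction.

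**Figure D4:**
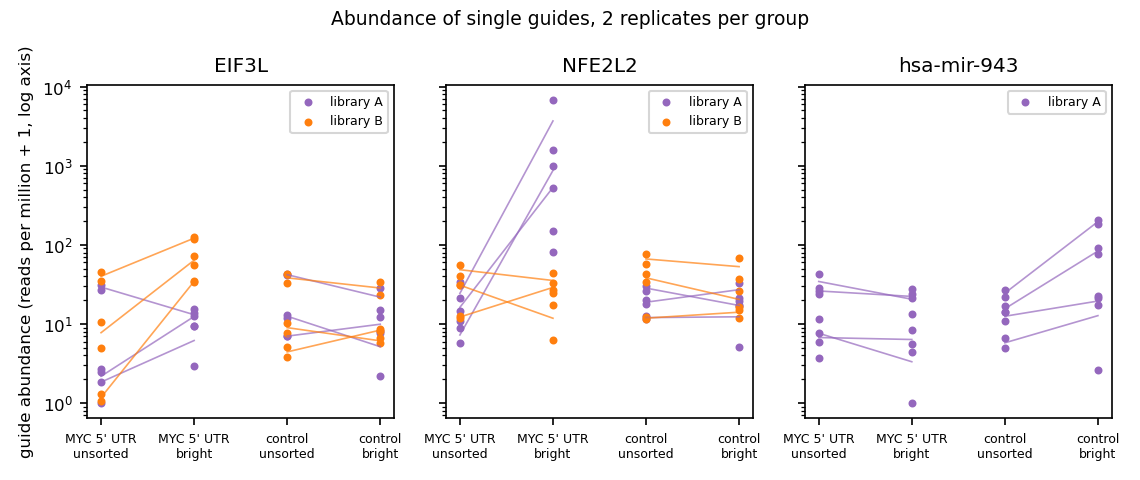
Abundance of each guide of EIF3L, NFE2L2 and hsa-mir-943 (y axis, RPM plus 1, log axis) in unsorted and bright cells of the MYC 5' UTR and control lines (x axis); points are the 2 replicates, lines join group means, purple is library A and orange library B. In bright MYC 5' UTR cells the library A guides of NFE2L2 reach up to 6827.5 RPM in replicate 1 and 521.8 RPM in replicate 2 for the same guide, while its library B guides have a mean change of -0.35.

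Unsorted cells of the 2 lines were compared to see whether the guide pools differed before sorting. Robust rank aggregation called 0 genes higher and 0 lower in the MYC 5' UTR line, with 1057 and 1051 at an unadjusted p under 0.05, and limma on gene means also called 0. The top-ranked genes were ITGB7 (0.97 ± 0.25), PDIA2 (1.69 ± 0.43), SNAI3 (1.11 ± 0.23), PLEKHN1 (0.86 ± 0.27) and C10orf114 (1.28 ± 0.22) on the higher side, each with adjusted p = 0.628. On the lower side they were FTH1 (-0.51 ± 0.38), TNFSF13 (-2.02 ± 0.48), SLC35E2 (-1.06 ± 0.22) and HTR3E (-0.96 ± 0.41), each with adjusted p = 0.642, and EIF3L (-1.53 ± 0.31, adjusted p = 0.659). EIF5A (-0.26 ± 0.40), DHPS (-0.15 ± 0.37), DOHH (-0.51 ± 0.49) and MYC (-0.06 ± 0.36) had adjusted p = 1, and without MYC 5' UTR unsorted replicate 2 EIF5A, DHPS and MYC had 0.28, 0.23 and 0.23. Camera passed 0 of 30 lists, with 2 at an unadjusted p under 0.05, and fry passed 0. The smallest adjusted p, 0.379, was shared by the initiation factors (mean -0.17) and microRNA biogenesis (mean 0.23).

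Replicates of the control line resembled each other more closely than those of the MYC 5' UTR line. Over 107636 guides, the Pearson correlation between unsorted replicates was 0.960 in the control line and 0.627 in the MYC 5' UTR line, and that between bright replicates was 0.588 and 0.440. The log2 SD of a guide between replicates was 0.93 (bright) and 0.28 (unsorted) in the control line. In the MYC 5' UTR line it was 1.43 and 1.01. The standard errors pool both lines, so they are likely too small for the MYC 5' UTR line and too large for the control line. The bright-over-unsorted change of replicate 1 against replicate 2 correlated at 0.407 (Spearman 0.455) in the control line and 0.243 (Spearman 0.262) in the MYC 5' UTR line. Both replicates were set against the same unsorted mean, and guides simulated without any effect gave 0.050 and 0.225. The shared controls may thus account for a small part of the value in the control line and for most of it in the MYC 5' UTR line. The covariance was 0.591 against a simulated 0.045 in the control line and 0.653 against 0.577 in the MYC 5' UTR line. With 1 unsorted replicate for each bright replicate, the correlation was 0.374 and 0.075, against simulated values of -0.002 and -0.003. Squared differences between replicates were 3.6 to 100.9 times the counting variance (chi-square per degree of freedom). Since PCR reads are not independent molecules, this ratio does not show how separate the replicates were. Guides are not independent replicates. The 978 non-targeting guides had a median change of -0.17 in the MYC 5' UTR line and 0.10 in the control line, before subtraction of the median gene.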

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

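The difference between the 2 reporter lines was planned and tested directly, while the tests of explanations in this part were chosen after the results were seen. By that test 2 genes (EIF3L and NFE2L2) were enriched more among bright cells of the MYC 5' UTR line than of the control line, and 1 locus (hsa-mir-943) was enriched less.

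NFE2L2 differed between the lines by 3.13 on the log2 scale. Loss of NFE2L2 acting through every guide is argued against, since the library B guides averaged -0.35 ± 0.29 against 5.87 ± 0.83 in library A, a gap of 6.22 where the largest among the other 10 called genes was 2.9 (DBR1). A single outside source of the 3 library A guides, such as carried-over material, may account for them: their ratio of bright replicate 1 to replicate 2 was nearly fixed, at 10.6 to 13.1, with a spread at the 0.87 percentile of 16875 guide trios and at 2.61 among the 844 most abundant. Independent chance expansion of single clones stays open for rises above 2 on the log2 scale in both replicates (3.09% of guides), where 0.5 genes with all 3 guides raised were expected and 2 were seen (NFE2L2 and SIX5), but is argued against for rises as large as the smallest of the NFE2L2 guides (6.1 in replicate 1 and 2.45 in replicate 2), which 7 of 50622 guides of other genes reached, so that 4.5e-08 such genes were expected. An effect of NFE2L2 loss through the library A guides alone was not tested.

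The locus hsa-mir-943 differed by -2.30, with enrichment in the control line. It lies inside NELFA, and cuts in that host gene are a candidate explanation, since the guides of NELFA itself had 2.04 ± 0.33 in control bright cells and a difference between lines of -2.12 ± 0.46. A rise shared by the 15 microRNA biogenesis genes is argued against, because they had a mean of 0.01 in control bright cells (SE 0.15 over members). A list mean can miss an effect of a few members, so it cannot decide on a general loss of mature microRNA. Loss of this one microRNA was not tested apart from the host gene.

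EIF3L differed by 3.09. Over both libraries, a lower starting level in unsorted MYC 5' UTR cells (-1.53 ± 0.31) is argued against as the whole cause. Bright MYC 5' UTR cells exceeded bright control cells by 1.55 ± 0.31, a value that is part of the difference by which EIF3L was picked. The excess came mainly from library B guides, with 32.9 to 123 RPM in bright MYC 5' UTR and 4.7 to 33.0 RPM in bright control cells. Library A guides had 1.98 to 14.4 and 1.23 to 27.6 RPM, so for them a lower start stays open as the whole cause. A shared effect of eIF3 subunits stays open: the 9 measured subunits left after EIF3L, EIF3F and EIF3H, whose values prompted the list, had a mean difference of 0.28, at the 90.18 percentile of 10000 matched random lists, with 7 above the median gene. The unsorted level of EIF3L had -1.59 and -1.52 without unsorted replicate 1 or 2 of the MYC 5' UTR line, and over all settings ranged from -2.04 (library A alone and limma voom) to -0.12 on the deposited scale, where the filter left out the guides with low counts, so that this value covers a smaller set of guides and is not a like-for-like change of setting.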

How the results depend on the processing

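The alternatives were planned, apart from the deposited scale, limma voom and single libraries for the lists, which were chosen after seeing the data; the cause of a change was not tested unless a setting removes guides or samples by its construction. For single genes and lists, 2267 values kept their direction and side of the threshold, 269 lost a call, 35 gained one and 25 turned sign. Guides without a read, up to 16.3% of library A, can show no further fall at this depth. Leaving out 1 replicate moved the enriched genes between 3 and 10 in the MYC 5' UTR line and 5 and 16 in the control line (0 to 1 depleted), the difference between 0 and 3 higher and 0 and 2 lower, and the lists between 1 and 5 and between 1 and 6; a group then held 1 sample, assumed to vary like the others. Counts for unsorted cells stayed at 0 under every setting run.

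The main settings called 11 enriched genes in the MYC 5' UTR line and 12 in the control line. Library A alone, which tests fewer guides, gave 2 and 5, of which 2 and 4 were among the main calls. Ranking by fold change gave 1 and 4, of which 1 and 1 were among them. Library B alone gave 3 and 2 and the strongest guide left out 3 and 2, all among the main calls, and a threshold of 0.25 gave 17 and 49. Limma voom gave 7 in the MYC 5' UTR line, 5 of them among the 11, and limma on gene means 2 in the control line. Depleted genes numbered 1 with library B alone and 4 by limma on gene means in the MYC 5' UTR line, and 1 with the samples of the comparison alone in the fit in the control line. For the difference, the 2 higher and 1 lower became 0 and 0 without a filter, with the strongest guide left out and by limma on gene means. The higher ones became 1 with either library alone, on the deposited scale, with limma voom and with ranking by fold change, which left 0 lower, and the lower ones became 4 at a threshold of 0.25. The 1 lower call with library B alone, and that on the deposited scale, was another gene. The locus hsa-mir-943 could not be tested in either setting. All its guides were in library A, and on the deposited scale the filter left it fewer than the 3 guides that a test required.

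Of 5 lists in the MYC 5' UTR line, 3 passed with pseudocount 20, 2 with library A, 3 with library B and 0 with an estimated correlation or fry; of 6 in the control line, 1 passed with pseudocount 1, 3 with library A, 1 with library B and 0 with an estimated correlation. The replicate correlation of the control line, 0.407, became 0.332 with pseudocount 1, 0.466 with pseudocount 20 and 0.492 for guides with a mean of at least 100.

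Signs turned mostly in genes without a call. In MYC 5' UTR bright cells, library B alone gave -0.35 for NFE2L2, -0.43 for COASY, 0.58 for BCL2L15 (0.34 with the strongest guide left out), 0.13 for GAB1 and -0.14 for DHPS, and MYC had -0.06 for guides with a mean of at least 100 and -0.21 with library A. In control bright cells, library A gave -0.01 for TAF8 and for DHPS. For the difference, EIF3H had -0.07 with library A, DHPS -0.45 with library B, and MYC -0.12 for guides with a mean of at least 100, -0.46 with library A and -0.09 to 0.53 with a replicate left out. For unsorted cells, EIF5A had 0.05 with library B and on the deposited scale and -0.84 to 0.28 with a replicate left out, DHPS 0.58 with library B and -0.57 to 0.23, MYC 0.29 with library A, 0.09 with the strongest guide left out and -0.38 to 0.23, and the hypusine pathway 0.06 with library B and -0.54 to -0.12.

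With the replicate number as a block, 9 genes were called in the MYC 5' UTR line (8 of the 11), 13 in the control line (11 of the 12) and the same 2 and 1 for the difference. The numbers were not treated as pairs, a choice fixed before the data were examined because the labels state no pairing. Deviations of same-numbered samples correlated at -0.002 and 0.006 (MYC 5' UTR line, libraries A and B) and -0.003 and 0.001 (control line). The block was not run for unsorted cells, where it coincides with the lines. edgeR and DESeq2 were planned and not run, although whole reads could be recovered; limma voom was run on those reads instead. Rescaling to the non-targeting guides covered library A, which holds all of them.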

Other observations

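The subunit lists and tests in this part were chosen after the values were seen, and the members whose values prompted a list were left out of its test. Of TFIID, the 9 subunits other than TAF1, TAF5, TAF7, TAF8 and TAF12 had a mean change of 0.43 in the MYC 5' UTR line, at the 98.62 percentile of 10000 random lists matched on abundance, with 7 above the median gene. In the control line the same 9 had 0.36, at the 98.68 percentile, with 8 above the median gene. TAF3 had 1.42 ± 0.31 in the MYC 5' UTR line and 1.89 ± 0.31 in the control line (adjusted p = 0.580 and 0.202), and TAF10 had 0.61 ± 0.29 and 0.48 ± 0.29. A large part of both means came from TAF3, most of all in the control line, and the list was not tested without it. TAF13 had 0.03 ± 0.26 and -0.79 ± 0.26. This is consistent with the hypothesis that loss of TFIID subunits raises the share of bright cells with either reporter, and does not separate an effect on the promoter of the reporter from one on cell size or growth.

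Of the negative elongation factor NELF, NELFA had 2.04 ± 0.33, NELFB 2.21 ± 0.42, NELFCD 1.61 ± 0.31 and NELFE 0.77 ± 0.38 in control bright cells. In MYC 5' UTR bright cells they had -0.09 ± 0.33, 0.26 ± 0.42, 0.91 ± 0.31 and 0.07 ± 0.38. NELFA, NELFB and NELFCD prompted the list, which left 1 subunit, NELFE, at the 99.12 percentile of matched random genes in control bright cells and at the 4.85 percentile for the difference between lines (-0.70 ± 0.53). With 1 subunit left, a shared effect of NELF loss, or one that differs between the reporters, stays undecided.

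For the SET1/MLL core, the 4 subunits other than ASH2L and DPY30 had a mean of 0.26 in the MYC 5' UTR line, at the 84.52 percentile of matched random lists, with 3 above the median gene. In the control line they had 0.37, at the 95.09 percentile, with 2 above the median gene. Both percentiles lay short of the bound set for the test, so a shared effect beyond ASH2L and DPY30 stays open. WDR5, another core subunit, had -1.12 ± 0.25 and -0.21 ± 0.25.

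Guides against EIF5AL1, a gene closely related in sequence to EIF5A, had 1.75 ± 0.43 in MYC 5' UTR bright cells (adjusted p = 0.287) and 0.29 ± 0.43 in control bright cells. EIF5A had 1.21 ± 0.40 and 0.63 ± 0.40. These values are consistent with guides of EIF5AL1 that also cut EIF5A, a hypothesis that guide sequences, not used here, would be needed to test further.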
